A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

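Total RNA of 4 cultures of the htr2 and ura3 deletion strain was measured on 8 two-colour arrays, as 4 dye-exchange pairs against a common NRC-1 reference, per the labels' protocols. The deposited scanner files give spot mean intensity and background median intensity for Alexa 532 and Alexa 647, each in a high-gain (H) and a low-gain (L) scan, per the file headers, with no background subtracted. Reading H and L as higher and lower gain rests on their values and is not stated in the sources used here. The deposited files also give a confidence score per spot, which followed saturation at 65535 and marked no other outliers, so no spot was left out by it. The authors' value table holds log10 ratios whose scale and direction are not stated. Set against the scanner values, each column correlated at 0.857 to 0.968 with log10 of Alexa 532 over Alexa 647 without background subtraction, once spots were put in physical order, and at 0.203 to 0.501 in the scanner's own numbering. The columns were not turned for the dye exchange. Their medians were 0.050, 0.052, 0.062, 0.0037, 0.047, 0.0099, 0.063 and 0.015 in the order high oxygen light, high oxygen dark, low oxygen light and low oxygen dark, replicate 1 before 2. The centring and background steps behind them stay unknown. Gene names follow the order of the value table, and were taken from the platform's annotation: 133 probes had 1 symbol, 0 had several and 2555 had none. An annotation table of another strain (assembly ASM479960v1) matched 0 of 133 gene identifiers and was not used. Control spots could not be told from other unnamed spots and stayed in.

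From the H scan, background was corrected by normexp with an offset of 50, log ratios were normalized by one loess curve per array (span 0.3), and the 4 spots of a probe were averaged. Ratios were turned to sample over reference by the dyes in the labels, and the 2 arrays of an RNA were averaged to 1 value. The correlation of the 2 arrays across probes was 0.20 to 0.34. Averaging a pair cancels a dye difference of a gene, so the SD of the 4 values does not show it. The 4 values were fitted in limma 3.58.1 (R 4.3.3) with oxygen and light as terms, which leaves 1 residual degree of freedom, with moderated variances (prior degrees of freedom 2.97 in the main setting, and infinite without background subtraction on the H scan, with the value table and with an intensity trend; infinite without a trend means one variance shared by all probes) and two-sided tests adjusted by the Benjamini-Hochberg method at 0.05. The interaction, the 2-fold counts and the ratio to the reference were given as values. The interaction is also the only residual of the fit. Of 31 gene lists fixed by symbol, 10 had at least 3 named probes and were tested with camera at a preset correlation of 0.01 and with an estimated one, 10 had 1 or 2 genes and 11 had none. With 1 residual degree of freedom the estimate took only coarse values, such as -0.33, 0.2 and 1, so the estimated version has little power.

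Named genes were chosen by a rule set before the data were examined. It takes the 12 largest positive and 12 largest negative oxygen differences, and 8 and 8 for light, among genes past the threshold with the same direction in both settings of the other factor and in both dye orientations. As none passed, the places were filled with the largest differences that had that agreement. For the reference it takes 8 highest and 8 lowest means with one sign on all arrays, and for the interaction 4 each way. It adds up to 4 members of each list, every measured member of the bacteriorhodopsin, phototaxis receptor and arginine fermentation lists, and htr2, pyrF and sop2. Here the places went to genes with a symbol, and 2 unnamed probes each way are given by position.

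On data simulated for the oxygen comparison over 2688 probes with the spread of the main setting, limma called 60% of probes changed by 1 (log2), 94% of those changed by 2, 0% of those changed by 0.5 and 2% of those changed by 0.25, with 1 false call. With the spread found without background subtraction and with loess in each printed set it called 72% at 0.25 and 100% at 0.5, with 8 false calls. Here every probe was simulated with one shared variance and independent noise, so this cannot test whether the shared variance holds.

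The share of spots at 1.5 times background or more in both channels was 46.2% and 46.5% on the high oxygen light arrays, 46.7% and 44.3% for high oxygen dark, 49.9% and 44.8% for low oxygen light, and 31.6% and 36.6% for low oxygen dark. At least 1 saturated reading occurred in 233 probes, 29 of them named. A slide-wide trend of ratios ran over the rows of printed sets, with a range of 0.34 to 0.91 (log2) per array. Alternatives changed background, normalization, averaging, the dim filter, moderation, the treatment of dye pairs and the arrays used. Several normalizations of both scans were looked at before the settings with loess in each of the 48 printed sets, the L scan and the omission of saturated probes or of the deleted genes from the lists were added, so these were chosen after seeing the data.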

Results

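Gene expression was measured in a strain of the halophilic archaeon Halobacterium salinarum NRC-1 that, per the labels, lacks htr2 and ura3. The htr2 product is the transducer that relays signals from sensory rhodopsin II, the receptor for repellent blue light. The ura3 gene, listed on the array as pyrF, encodes orotidine 5'-phosphate decarboxylase, a late enzyme of pyrimidine synthesis. Cultures of 50 mL in flasks of 125 mL were grown in rich medium to mid-log phase under 4 conditions, with shaking at 210 rpm (high oxygen) or 100 rpm (low oxygen), each in light or in a darkened flask. Each condition gave 1 RNA sample. Each RNA was hybridised on 2 arrays with the dyes exchanged, against one standard RNA of mid-log NRC-1 labelled with the other dye. The 8 arrays therefore hold 4 independent RNA samples, 2 at each oxygen level and 2 at each light level. Nothing in the labels gives repeat cultures of a condition, so the spread between cultures was not measured. The only residual of the fit is the difference of the oxygen effect between light and dark, moderated over probes. The SEs and p-values for oxygen and light therefore measure that difference, and a real interaction would enlarge them. The array carried 2688 probes in 4 spots each. A gene symbol was available for 133 of them, and the other 2555 are unnamed here. The median probe lay at 1.46 times the local background in the sample channel and at 1.48 times in the reference channel, and the number of arrays limits the precision further.

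The deleted genes were read first. The htr2 probe gave a lower signal than the reference on all 8 arrays, with a mean log2 ratio of -0.38 ± 0.09 (SD, n = 4 RNA samples) and single arrays between -0.58 and -0.15. The pyrF probe was lower on all 8 arrays too, at -0.61 ± 0.23 (SD, n = 4), with arrays between -1.12 and -0.14. The parts of the genes that were deleted, and the parts the probes cover, are not given in the sources used here. The pyrF probe was not well above background, at 1.10 times the local background in the sample channel and 1.36 times in the reference channel. The htr2 probe stood at 2.75 times background in the sample channel and 3.41 times in the reference channel. Genes that were not deleted, such as thiL and folP, both at -0.45, lay lower than htr2, so its ratio alone does not show the deletion. The neighbouring partner of htr2, sop2, which encodes sensory rhodopsin II itself, had a mean ratio of 0.12 ± 0.04 (SD, n = 4) and was higher than the reference on 6 of 8 arrays. Across background and normalization settings htr2 ran from -0.39 to -0.24, pyrF from -0.66 to -0.27 and sop2 from 0.050 to 0.15.

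Relative to the NRC-1 reference, both measured genes of arginine fermentation were higher in the strain under every condition. The ratio of arcA, which encodes arginine deiminase, was 0.38 ± 0.06, and that of arcC, which encodes carbamate kinase, was 0.38 ± 0.09 (log2, SD, n = 4 RNA samples). Of the 5 genes listed for phototaxis receptors and halorhodopsin, 2 were higher on all 8 arrays: hop, the chloride pump halorhodopsin, had a ratio of 0.34 ± 0.07 and sop1, sensory rhodopsin I, 0.24 ± 0.08. In the same list htr1 stood at 0.15 ± 0.07 and was higher on 7 of 8 arrays, sop2 was higher on 6 of 8, and the deleted htr2 was lower on all 8. Of the chemotaxis genes, cheB at 0.21 ± 0.05, cheA at 0.18 ± 0.05 and cheR at 0.12 ± 0.04 were above the reference on all 8 arrays, and cheY at 0.17 ± 0.08 on 7 of 8. The proteasome-activating nucleotidase gene pan1 at 0.25 ± 0.16 and the excision repair gene uvrB at 0.17 ± 0.03 complete the 8 highest ratios among named genes with the same sign on all 8 arrays. Across the same settings pan1 ran from 0.018 to 0.28, cheY from 0.066 to 0.19, htr1 from 0.12 to 0.23, cheB from 0.046 to 0.26, cheA from 0.066 to 0.21, cheR from 0.040 to 0.15, hop from 0.19 to 0.36 and sop1 from 0.13 to 0.27, while arcA stayed between 0.28 and 0.44 and arcC between 0.28 and 0.42.

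Among named genes with the same sign on all 8 arrays, the lowest ratios were those of the ribosomal protein genes rpl12p and rpmC, at -0.64 ± 0.17 and -0.63 ± 0.12 (log2, SD, n = 4 RNA samples), followed by the deleted pyrF. The translation initiation factor gene infB stood at -0.40 ± 0.04. Of the spot readings of rpl12p, 25 of 64 were saturated, and of those of arcA 3. Of 17 genes tracked against the reference across settings, 13 remained when probes with saturated readings were left out. The thiamine gene thiL stood at -0.45 ± 0.06, the folate gene folP at -0.45 ± 0.10 and sucC, a subunit of succinyl-CoA synthetase, at -0.39 ± 0.18. In the citrate cycle list 3 of 5 genes were lower on all 8 arrays, among them citZ at -0.16 ± 0.03 and sucD at -0.20 ± 0.05. Across the same settings thiL ran from -0.48 to -0.20, folP from -0.48 to -0.23, infB from -0.45 to -0.23, citZ from -0.18 to -0.080 and sucD from -0.31 to -0.16, while rpl12p stayed between -0.83 and -0.52 and rpmC between -0.66 and -0.51. Over all probes, 494 of 2688 had the same sign on all 8 arrays, which share 4 RNA samples and one reference. Of the named genes, 9 were higher and 28 lower on all 8. A mean of at least 2-fold was reached by 8 probes, all lower and none named. The lowest were position_1605 at -2.32 and position_1547 at -2.18. The highest unnamed means were those of position_1229 at 0.96 and position_2475 at 0.92. The reference is one RNA pool and not a matched culture, so the strain was not tested against it.

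**Figure D1:**
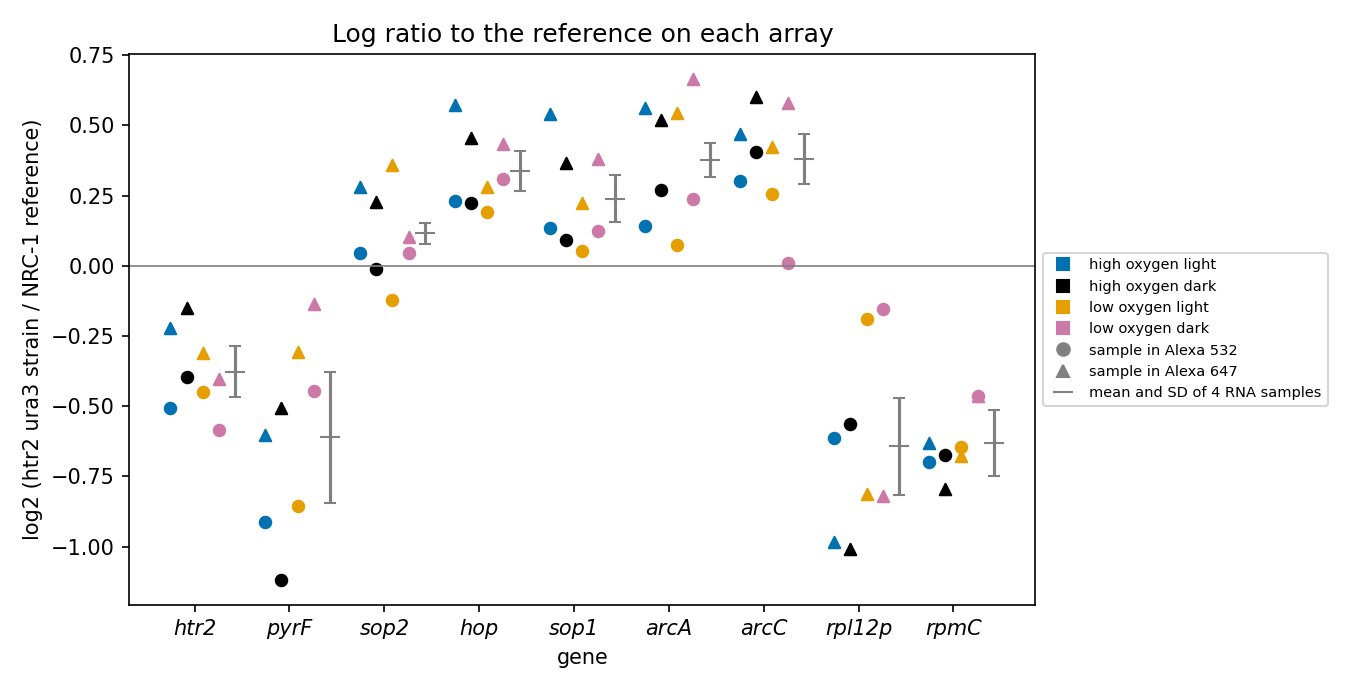
Log2 ratio of the deletion strain to the NRC-1 reference for 9 named genes, with 1 point per array, colours for the 4 conditions, symbols for the dye of the sample, and grey bars for the mean and SD of the 4 RNA samples. The genes htr2, pyrF, rpl12p and rpmC lie below 0 on all 8 arrays, while hop, sop1, arcA and arcC lie above 0 on all 8.

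The effect of oxygen was estimated as low minus high, with light as a covariate. No gene passed the limma test at an adjusted p of 0.05: the smallest adjusted p was 0.61, and 212 of 2688 probes had an unadjusted p under 0.05, where chance gives 134.4. The ribosomal gene rpl12p showed a difference of 0.30 ± 0.09 (log2, SE; 2 RNA samples per level), with 0.30 in light and 0.30 in the dark, and between 0.18 and 0.52 across settings. The sucC difference was 0.30 ± 0.10, with 0.25 in light and 0.36 in the dark, and that of carB, carbamoyl phosphate synthetase, was 0.25 ± 0.09. These values were positive in both dye orientations, and none of them passed. Without background subtraction rpl12p and sucC passed, each with a limma adjusted p of 0.026. Over all alternatives the limma adjusted p ran from 3.7e-06 to 0.98 for rpl12p, past the threshold in 4 of 20, and from 0.0074 to 0.91 for sucC, past it in 3 of 21. In the settings without background subtraction on the high-gain scan limma gave every probe one shared variance, with an SE of 0.076 for rpl12p and sucC, or 0.065 with loess in each printed set.

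Other positive differences were 0.46 for uvrA, 0.35 for pyrF, 0.34 for bat, the activator gene of bacterio-opsin, 0.32 for the seryl-tRNA synthetase gene serS, 0.27 for the glycerol kinase gene glpK, 0.23 for cysS, 0.20 for gyrB and 0.18 for panB. The pyrF value comes from a gene deleted in the strain. Agreement in direction did not mean like sizes: serS had 0.07 in light and 0.57 in the dark, and glpK 0.10 and 0.45. For bat the values were 0.30 and 0.38, and for cysS 0.27 and 0.19. The low oxygen light arrays of uvrA read -0.51 and 0.96. Across background and normalization settings uvrA ran from 0.0066 to 0.59, bat from 0.066 to 0.36, serS from 0.14 to 0.35, cysS from 0.024 to 0.26, gyrB from 0.057 to 0.28 and panB from 0.076 to 0.21. Negative differences included -0.30 for endA and -0.23 for purD. Smaller ones were found for dnaK at -0.15, cheY at -0.13, arcC at -0.13, htr2 at -0.12, surE at -0.11, deoC at -0.11 and pheS at -0.09. Across settings purD ran from -0.27 to -0.096 and dnaK from -0.16 to -0.014. The genes hutI, tmk, purB and hutG also met the rule, but their probes lay below the local background in both channels, so no difference is given for them in any setting. Of the 20 genes given values 9 changed direction in at least one setting, namely pyrF, glpK, endA, cheY, arcC, htr2, surE, deoC and pheS. The changed values reached only 0.0030 for cheY, 0.0020 for pheS and -0.0065 for glpK, but 0.080 for htr2 and 0.072 for endA. For arcC the direction changed only with an array left out, where a dye difference no longer cancels. By dye arcC had -0.22 (Alexa 532) and -0.031 (Alexa 647). Of all 24 genes, chosen for agreement in light, in dark and in both dye orientations, 10 lay under 1.5 times background in both channels, including bat, uvrA and pyrF. That agreement was met by 42.1% of the named genes and 39.1% of all probes. Independent simulated noise gives 33.1%, but the arrays of a pair share an RNA, so this is not the chance level here. No probe differed by 2-fold or more in both light and dark.

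The lists fixed before the data were examined gave no oxygen effect either, with 0 of 10 tested lists past the threshold in camera. All 5 genes of pyrimidine synthesis, the deleted pyrF among them, had positive differences, with a median of 0.13 and a camera adjusted p of 0.15, or 0.85 with an estimated correlation. Its members pyrI at 0.13 ± 0.10, pyrB at 0.09 ± 0.10 and carA at 0.05 ± 0.10 (SE) did not pass, and 36 of 64 readings of pyrI and 32 of 64 of pyrB were saturated. Without probes that had saturated readings, 3 genes were left, with an adjusted p of 0.28. The list's adjusted p was 0.0085 without background subtraction and with loess in each printed set, a setting chosen after the data were seen, with 4 of 5 genes positive, and its adjusted p = 0.95 there with an estimated correlation. With the authors' value table and with the low-gain scan processed in that way 2 of 5 were positive, with adjusted p-values of 0.78 and 0.87. Over 18 alternatives that list's camera adjusted p ran from 0.0085 to 0.87 and passed in 3. With an estimated correlation the adjusted p in those 3 was 0.80 to 0.97. That version has little power with a single residual degree of freedom, so it decides nothing about them. Across settings pyrI ran from -0.058 to 0.37, pyrB from -0.14 to 0.32 and carA from -0.084 to 0.099. Without the deleted gene, a choice also made after the data were seen, the adjusted p was 0.31 in the main setting and the list passed in 1 of those 3 settings, at 0.043. In purine synthesis 6 of 7 genes had negative values, with a median of -0.063 and an adjusted p of 0.31. The number positive was 1 of 7 with scale normalization, 3 without background subtraction and with median centring, and 4 with the low-gain scan. All 4 DNA repair genes were positive, with an adjusted p of 0.31, among them mutL at 0.18, between 0.0045 and 0.18 across settings, and radB at 0.07. Of 5 genes for phototaxis receptors and halorhodopsin, 4 were negative, with an adjusted p of 0.48: the deleted htr2 stood at -0.12, sop1 at -0.09, hop at -0.07, sop2 at -0.04 and htr1 at 0.01. Of these 5, 0 were positive without background subtraction and 3 with the low-gain scan. Across settings sop1 ran from -0.087 to 0.021, hop from -0.21 to -0.046 and sop2 from -0.039 to 0.077. Citrate cycle genes other than sucC were near 0, with sucD at 0.06, up to 0.27 across settings, and mdh at 0.03. Of the arginine fermentation genes, arcA had a difference of 0.01 ± 0.10 and arcC one of -0.13 ± 0.10 (SE), and arcA ran from -0.12 to 0.12 across settings. No member of any list passed over all genes or adjusted over the list alone. Gas vesicle, DMSO respiration and ATP synthase lists had no named probe.

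**Figure D2:**
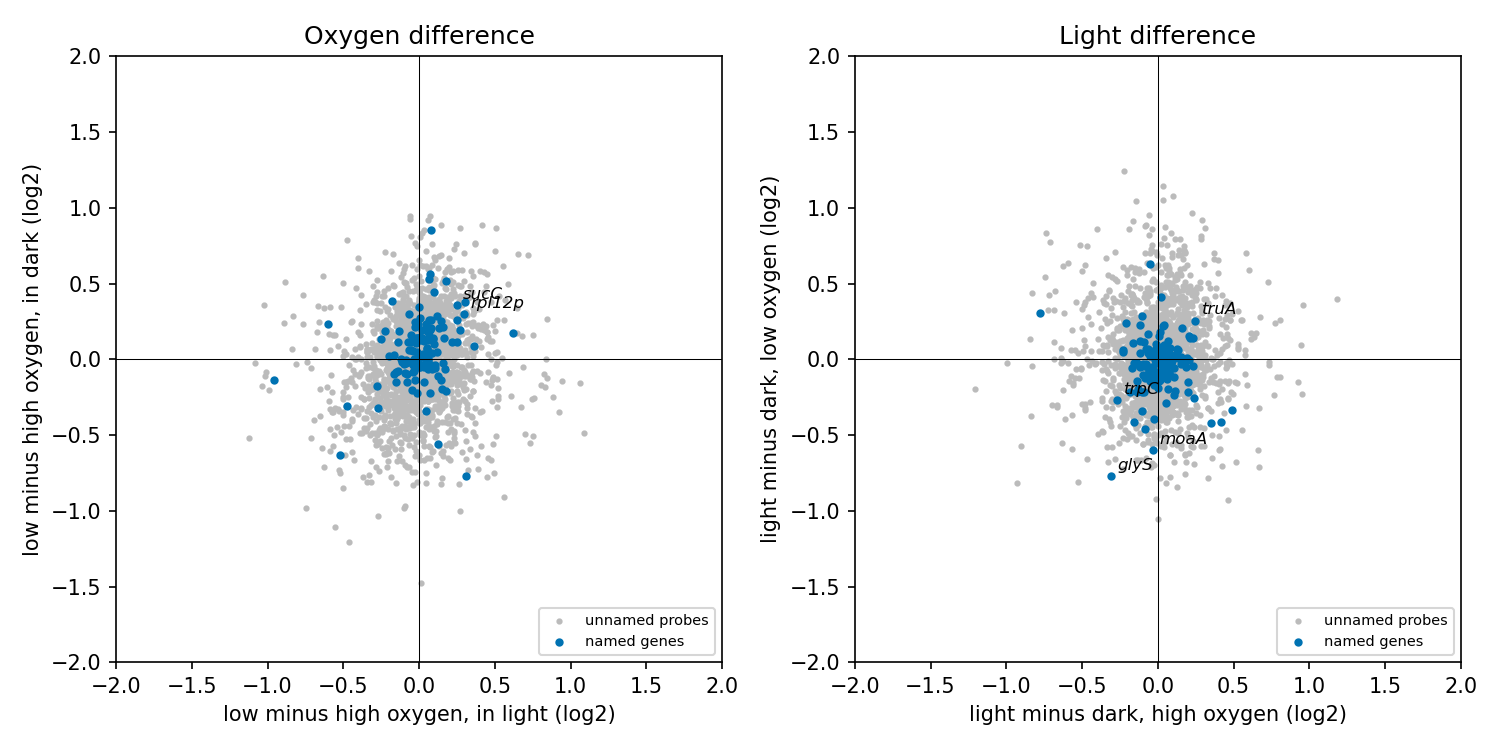
Differences in log2 ratio for 2688 probes, with oxygen (low minus high) in light against in dark on the left and light (light minus dark) at high against at low oxygen on the right, in grey for unnamed probes and blue for named genes. The oxygen differences correlate across probes at r = 0.14 and the light differences at r = 0.014.

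The effect of light was estimated as light minus dark, with oxygen as a covariate. No gene passed the limma test at an adjusted p of 0.05, the smallest adjusted p being 0.91, and 126 probes had an unadjusted p under 0.05 against 134.4 by chance. The largest named difference was that of glyS, glycyl-tRNA synthetase, at -0.54 ± 0.15 (log2, SE; 2 RNA samples per level), with -0.31 at high and -0.77 at low oxygen. The low oxygen dark arrays read 0.85 (replicate 1) and 0.34, and the low oxygen light arrays -0.37 and 0.016, so replicate 1 weighs heavily. The glyS probe lay at 1.14 times background in both channels. It passed in limma without background subtraction, at -0.31 with an adjusted p of 0.032, and with the authors' value table. Over the alternatives its limma adjusted p ran from 0.0091 to 0.96. The transducer gene htr18 was below background in both channels and is given no value. The gene moaA of molybdenum cofactor synthesis had -0.32, trpC -0.27, pan1 -0.22, hisD -0.21, purM -0.20 and bat -0.18. Across background and normalization settings the value nearest 0 was -0.15 for moaA, -0.056 for trpC, -0.087 for pan1, -0.037 for hisD, -0.047 for purM and -0.011 for bat. Positive values were 0.25 for truA, 0.21 for the transducer gene htr6, 0.19 for leuS, 0.18 for cmk, 0.18 for panB, 0.18 for purF, 0.13 for radB and 0.13 for dnaJ. The lowest across settings were -0.00057 for truA, 0.096 for htr6, 0.037 for leuS, 0.069 for cmk, 0.11 for panB, 0.064 for purF, -0.12 for radB and 0.0062 for dnaJ. In the main setting htr6 had 0.020 at high and 0.41 at low oxygen, while truA had 0.25 and 0.26. Of these 16 genes, 7 were under 1.5 times background in both channels. None of 10 lists passed in camera: 5 of 5 pyrimidine genes and 5 of 6 cobalamin and heme genes had negative values, each with an adjusted p of 0.91, or 0.96 with an estimated correlation. The light differences of sop2 and hop were 0.05 and -0.04, that of sop1 was -0.0033, and those of htr1 and htr2 were 0.05 and 0.01. Across settings sop2 ran from 0.017 to 0.14, hop from -0.036 to 0.084 and htr2 from -0.19 to 0.050.

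Whether oxygen acted differently in light and dark could not be tested with 1 RNA sample per condition. The largest named values of the oxygen difference in light minus that in dark belonged to gatC, htr4, hutI and srp19 on one side and to nadA, purB, uvrA and moaA on the other. Of these 8 genes, 7 lay under 1.5 times background in both channels. The probes of gatC, hutI, nadA and purB lay below the local background in both channels and are given no value. The values were 0.68 for htr4, 0.39 for srp19, -0.77 for uvrA, whose sign differed between dye orientations, and -0.57 for moaA. Across all probes the interaction from the arrays with the sample in Alexa 532 and that from the arrays with it in Alexa 647 correlated at r = -0.039. Over all probes, 37 had a value of at least 1 in size with the same sign in both dye orientations, and 2 when the dimmest 25% of probes were left out.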

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

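The tests of a slide trend, of probe copies on opposite parts of the slide and of the deleted genes' signal were chosen only after the result was seen. Of the named interaction genes, 3 had oxygen differences of opposite direction in light and dark on both dye orientations, and the difference was not tested. These were htr4 at 0.68, srp19 at 0.39 and moaA at -0.57 (difference in light minus in dark, log2). Among all 133 named genes 13 had such opposite signs, where independent signs give 12.5% or 16.6 genes. The arrays of a pair share an RNA, so this is not the chance level here. The 3 genes come from 8 picked for a large value.

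The oxygen difference correlated across probes between light and dark, which are separate RNA samples, at r = 0.14 (probes are not independent replicates). It was 0.070 without high oxygen dark replicate 2, 0.088 without high oxygen light replicate 1, 0.090 without low oxygen dark replicate 1, and 0.31 without background subtraction and with loess in each printed set. The light difference at high and at low oxygen gave 0.014 in the main setting and 0.23 with the authors' value table. A trend across the slide is argued against by r = 0.17 with loess in each printed set, and saturated or bright spots by r = 0.14 over the 2013 probes without them. A batch of arrays could still produce it: probes under 1.5 times background gave 0.14 and brighter ones 0.17, and array numbers run with oxygen, so batch and an oxygen response of the cells cannot be told apart.

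Calls appeared when the background was not subtracted, with 30 positive and 22 negative for oxygen under loess in each printed set. Noise from the subtraction is one candidate cause. With one curve per array the test spoke against it: copies of a probe on opposite parts of the slide correlated at 0.30 with subtraction and 0.20 without. With loess in each printed set the order was the opposite, 0.42 with and 0.61 without, and this second comparison was added after the first had been seen. A spread estimated too small for every contrast would give calls for the interaction as well: with light in the residual it gave 2 against 52. A batch that runs with oxygen would raise the oxygen calls alone, so this test cannot exclude a spread too small for oxygen. The first version of that test, with oxygen in the residual, gave 0 and decides nothing because the oxygen differences enlarge that residual.

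The deleted genes differed from the reference by less than 2-fold. For pyrF a probe near background may be the reason, since its reference channel lay at 1.36 times background. For htr2 this is excluded by a reference channel at 3.41 times background. Its sample channel at 2.75 times background is consistent with signal from other transcripts, and a probe outside the deleted part would look alike. No biological explanation was tested.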

How the results depend on the processing

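Loess in each printed set, the low-gain setting, omission of saturated probes or deleted genes and the estimated correlation in each setting were chosen after seeing the data. The low-gain setting also drops background subtraction, adds 50 and uses loess in each printed set, so the scan alone was not tested. Signal over background is one limit: 1330 of 2688 probes and 29 of 133 named genes lay under 1.5 times background in both channels. The cause of the changes below was not tested. The 0 oxygen calls became 19 without background subtraction (9 positive, 10 negative), 6 with the authors' value table and 11 with an intensity trend. They stayed 0 with 8 independent arrays and a dye term. They were 52 without subtraction under loess in each printed set and 18 in the low-gain setting. With RNA as a random block 51 passed, but a within-pair correlation of -0.52 lowers the SE, so these decide nothing. Leaving out one array gave 0 to 2 oxygen calls, the 2 without low oxygen dark replicate 1. Light calls, 0 in the main setting, were 3 without background subtraction under either loess, 23 with the value table, 1 with an intensity trend, 11 in the low-gain setting and 0 to 1 with one array left out, the 1 without low oxygen dark replicate 1. Scale normalization gave 1 probe of 2-fold for oxygen and 1 for light, and leaving out one array gave 0 to 1 for light. The 8 probes 2-fold from the reference were 3 without background subtraction, 2 with the value table, 4 without subtraction and with loess in each printed set and 5 in the low-gain setting. The 37 interaction probes were 0 without subtraction under either loess and with the value table, 2 without the dimmest 25% of probes, 22 with loess in each printed set and 2 in the low-gain setting. Pyrimidine synthesis passed as the 1 oxygen list without subtraction, with one loess curve or loess in each printed set, and with median centring. In that order its camera adjusted p was 0.97, 0.95 and 0.80 with an estimated correlation. Without the deleted pyrF it was 0.12, 0.043 and 0.085. For light, 3 lists passed with the authors' values, citrate cycle, chemotaxis and chaperones, each with an adjusted p of 0.72 with an estimated correlation. The estimated version has little power here and decides neither these lists nor pyrimidine synthesis.

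The genes hutI, tmk, purB, hutG and htr18, below background in both channels, are given no value in any setting, a choice made after seeing the data. Of the other 20 oxygen genes 9 changed sign in some setting, and 2 of 15 light genes. In the low-gain setting oxygen values were -0.020 for pyrF, -0.0065 for glpK, 0.080 for htr2, 0.024 for surE and 0.0012 for pheS, and light values were -0.00057 for truA and -0.12 for radB. With the value table they were 0.059 for htr2, 0.0075 for deoC and, for light, -0.042 for radB. The median of spots gave 0.072 for endA, median centring 0.0030 for cheY, and no subtraction with loess in each printed set 0.0020 for pheS. With one array left out arcC ranged from -0.27 to 0.017, the positive value without low oxygen dark replicate 1. The range of deoC was -0.31 to 0.086, positive without that array (0.044) and without low oxygen light replicate 2. None of 17 genes tracked against the reference changed sign, but 53 of their values moved by more than the SD between RNA samples. These included 11 with the value table and 11 without subtraction under loess in each printed set. No paired analysis was possible because the replicate numbers only name the dye orientation and the arrays of a pair hold the same RNA. Keeping outlier-marked spots and leaving out plasmid genes were not run, as no outliers are marked and replicons were not used. Leaving out a whole RNA sample leaves no residual degrees of freedom.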

Other observations

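Beyond the genes above, chosen after their values were seen, argH of arginine synthesis had a mean ratio to the reference of 0.40 ± 0.04 (log2, SD, n = 4 RNA samples) and was higher on 7 of 8 arrays. All 6 genes of cobalamin and heme synthesis had negative means in the main setting. Only 1 of the 6, cbiT, was lower on all 8 arrays, at -0.36 ± 0.07 and from -0.40 to -0.17 across settings. The mean of hemA was -0.54 ± 0.12. Its arrays read -0.29 to 0.027 with the sample in Alexa 532 and -0.98 to -0.77 with it in Alexa 647. The SD does not show this dye difference. With loess in each printed set 1 of the 6 was above the reference. The surface glycoprotein gene csg was saturated in 64 of 64 spot readings, so its ratio of 0.09 has no meaning as a level.

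The value of the proteasome gene psmA depended on the processing. For oxygen it was 0.34 with a limma adjusted p of 4.5e-05 without background subtraction and with loess in each printed set, and 0.96 with the low-gain scan processed in that way with 50 added. In that setting it passed for light too, at 0.88 with a limma adjusted p of 0.0018, and its ratio to the reference was -0.46. Across settings its light difference ran from -0.12 to 0.88 and its ratio to the reference from -0.46 to 0.055. In the main setting its oxygen difference was 0.06 ± 0.09 (SE; 2 RNA samples per level), and 13 of its 64 readings were saturated. For oxygen its limma adjusted p ran from 4.5e-05 to 0.996 over 20 alternatives, past the threshold in 2.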
